A study of Rattus with 6 samples.

How the data were processed

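RNA was measured by sequencing in 6 libraries of cultured bone marrow mesenchymal stem cells of Sprague Dawley rats, 3 from animals with a model of chronic kidney disease (CKD) and 3 from healthy controls. Poly-A selected, stranded libraries were made, per the labels' protocols. The labels' extract protocol speaks of exosome RNA while the series' design text speaks of RNA from the cells, and which of these was sequenced is not settled here. Tools named in the submitters' processing notes are FastQC 0.11.9, HISAT2 2.1.0, SAMtools 1.9, HTSeq 0.11.2, DESeq2 1.22.2 and DESeq 1.34.1, with the rat build mRatBN7.2. These notes give neither the order of the tools nor their settings.

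The authors deposited 1 table of 16690 genes, with an FPKM value (fragments, normalized for gene length and library depth) for each gene and library, a mean normalized count per group, a fold change, a log2 fold change, a p-value and a q-value, per the file headers. Its numbers are written with decimal commas. The lowest mean normalized count over all libraries was 1.03, so genes with fewer fragments are not covered. The deposited q-values differed from Benjamini-Hochberg values recomputed from the deposited p-values by at most 1.55e-06. Gene names were taken from the table, and 16123 of its gene identifiers were found in a reference gene table of another assembly (GRCr8), used for older symbols only. No coordinates are given for that reason.

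The fragment counts behind the FPKM values were recovered from the table. The group means of normalized counts and the FPKM values together fix the ratio of size factor to depth in each library, and the smallest step of each library then fixes the worth of 1 fragment. All 100140 values came out whole within a tolerance of 0.01, with a largest deviation of 0.000514. Recovered depth was 38586674, 34404037 and 43055203 fragments in CKD replicates 1, 2 and 3, and 46892613, 41742848 and 38289955 in control replicates 1, 2 and 3. For a gene of median length, 3 fragments were worth between 0.0198 and 0.0270 FPKM, so values under that level rest on counting error. The recovered counts were used for depth, for the comparison of libraries with each other and for alternatives, and the main test was run on FPKM.

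Libraries were grouped by title, library name and column code. The disease model tag in the labels goes against these in CKD replicate 1, tagged as control, and in control replicate 2, tagged as CKD. Replicate numbers follow the column codes, and the title of CKD replicate 3 carries the number 4 instead. Library names that share a start (CKD replicates 1 and 3, and control replicates 1 and 2) leave open whether those libraries come from separate animals. Nothing in the labels ties each library to its own animal or culture, so p-values measure the spread between these libraries, which may be partly technical. Every pair of libraries differed by more than sampling noise (chi-square per degree of freedom of at least 5.53), which does not make them separate animals. The value was 14.1 for CKD replicates 2 and 3 and 5.53 for control replicates 2 and 3, against 139 or more for every other pair. Whether the members of these alike pairs are independent is open, and each library counted as 1 replicate.

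CKD was compared with control by limma 3.58.1 (R 4.3.3) on log2(FPKM + 1), with a mean-variance trend, no covariates, a two-sided moderated test and Benjamini-Hochberg adjustment at 0.05. A count model had been planned as the main test and this fit as its substitute for a table without counts. Genes with at least 1 FPKM in at least 3 libraries were tested, 10638 in all, and 6052 were left out. This filter was set after the table had been seen and before any test was run. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes.

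Before the data were examined, 31 gene lists with 616 members were fixed, covering differentiation, other cell types, proliferation, inflammation, matrix, metabolism and sample checks. Of the members, 557 were found in the table, and 25 lists had at least 5 tested genes. These were tested with camera (limma) at a preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry for a shared direction. Named genes follow a rule fixed at the same time. It takes the 10 called genes with the largest change in each direction that have an assigned symbol, groups that do not overlap and a mean normalized count of at least 50 in the higher group. It adds up to 4 called members per list with the lowest adjusted p, and 14 genes whatever their p, namely Itgb1, Thy1, Cd34, Ptprc, Runx2, Sp7, Alpl, Bglap, Spp1, Mgp, Pparg, Sox9, Cdkn1a and Cdkn2a. FPKM stood in for the CPM that the rule names, and the rule gave 49 genes. Any other gene named was chosen after its values were seen.

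The fit was tested on simulated fragment counts for CKD against control, turned into FPKM, with 200 genes changed by known folds. With each gene's own dispersion, 60.4% of the 2-fold and 81.8% of the 4-fold changed genes were called in the right direction over 10723 tested genes, with 6 false calls. With the median dispersion in every gene, all were called, with 21 false calls over 10798 tested genes. The list test (camera in limma) gave an adjusted p of 2.95e-77 for a list of 25 genes raised 2-fold and of 0.826 for an unchanged list. Simulated genes varied independently, so this check says nothing about lists whose genes vary together. In the 6 libraries the estimated correlation was 0.823 for the proliferation list, 0.940 for the haematopoietic list and 0.217 for the sterol synthesis list.

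Alternatives covered the filter, a pseudocount of 0.1, a fold change minimum, each library left out in turn, the replicate number as a block, grouping by the disease model tag, both libraries with conflicting tags left out, libraries with a shared name start summed, and limma-voom with sample quality weights on recovered counts. Others were added after seeing the data, namely limma-voom without weights, scaling by size factors or upper quartile, a term for the first replicates, the first replicates left out, CKD replicates 2 and 3 left out, the mean of the haematopoietic list as a covariate, and fry's mixed test. Figures were drawn with matplotlib 3.10.9.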

Results

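Gene expression was measured by RNA sequencing in bone marrow mesenchymal stem cells, the adherent stromal cells of the marrow that can form bone, fat and cartilage. Cells from rats with a model of chronic kidney disease (CKD) and from healthy control rats gave 3 libraries each. On the RNA that was sequenced the labels disagree, naming the cells in the series' design text and exosomes in the extract protocol, and wherever the libraries are called cells here this follows the design text and the titles. The recovered depth ran from 34404037 to 46892613 fragments per library, and 10638 genes were tested. The series concerns vesicles released by these cells in CKD and the calcification of vessels, and the comparison asks how transcripts differ between libraries of diseased and of healthy animals.

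Libraries did not fall apart by group alone. CKD replicates 2 and 3 were close to each other (Pearson r = 0.996 across genes), as were control replicates 2 and 3 (r = 0.998). The remaining library of each group stood apart. CKD replicate 1 was closer to each control (r = 0.967, 0.950 and 0.946 with control replicates 1, 2 and 3) than to CKD replicate 2 (r = 0.935) or CKD replicate 3 (r = 0.944). Genes are not independent replicates, so these correlations describe the libraries only. The first principal component held 58.2% of the variance and placed both first replicates between the other pairs, while the second held 27.8% and separated the first replicates of both groups from the other 4 libraries.

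**Figure D1:**
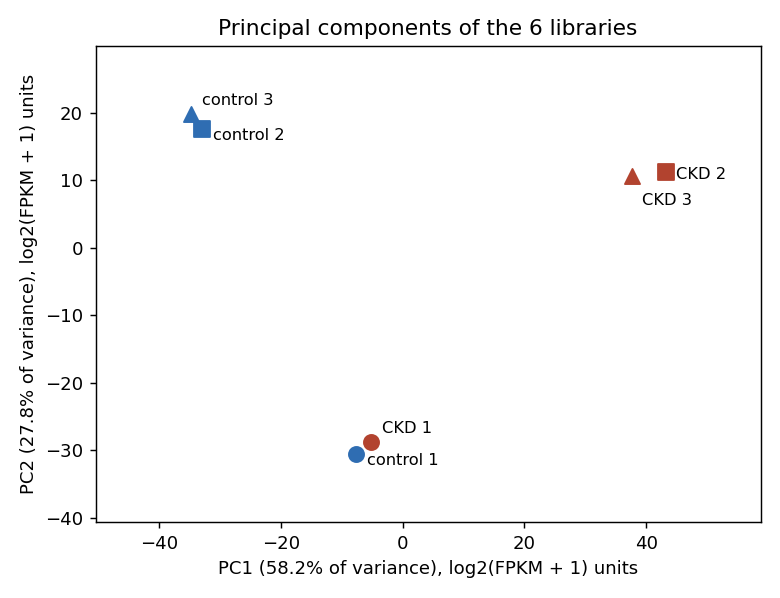
Principal components of the 6 libraries on log2(FPKM + 1) of 10638 tested genes, with PC1 on the x axis and PC2 on the y axis, both in log2(FPKM + 1) units. Each point is a library, coloured by group, and CKD 1 and control 1 lie together at PC2 values of -28.8 and -30.6.

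In CKD, 142 genes were higher and 78 were lower than in control. The largest called rise was that of H19 (NCBI Gene 309122), an imprinted long non-coding RNA, which averaged 77.0 ± 61.8 FPKM in CKD and 0.0396 ± 0.0259 FPKM in control (SD, n = 3 each; log2 fold change 5.69 ± 0.85 SE, limma adjusted p = 0.0439). Cdh13 (NCBI Gene 192248), which encodes T-cadherin, averaged 36.2 ± 9.30 FPKM in CKD against 3.09 ± 2.28 in control, and Cdh2 (NCBI Gene 83501), which encodes N-cadherin, averaged 13.3 ± 1.98 against 1.25 ± 0.625. On the falling side, Stmn2 (NCBI Gene 84510), a regulator of microtubules best known from neurons, averaged 0.212 ± 0.158 FPKM in CKD and 29.7 ± 8.47 in control (log2 fold change -4.64 ± 0.21 SE, limma adjusted p = 0.0028).

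Other genes with large called rises were Smoc1, a matrix protein related to SPARC (log2 fold change 2.75 ± 0.21 SE), the protocadherin gene Pcdh20 (2.60 ± 0.20), the LIM domain gene Lmcd1 (2.55 ± 0.38), Igfbp2, which binds insulin-like growth factors (2.28 ± 0.23), the matrix gene Hmcn1 (2.28 ± 0.27) and P2ry6, a nucleotide receptor (2.06 ± 0.22). Lyc2, a lysozyme gene, had a log2 fold change of 2.81 ± 0.41. It has a close relative in Lyz2, so fragments of the 2 genes could be shared and its value is uncertain. Large called falls were those of Tnfsf18, a ligand of the tumour necrosis factor family (-2.95 ± 0.41), the nuclear receptor gene Rorb (-2.32 ± 0.32), Adamtsl1 (-2.29 ± 0.08), Mfap5, a protein of microfibrils (-2.25 ± 0.33), and Pla2g2a, a secreted phospholipase (-2.24 ± 0.12). Pdia5, a disulphide isomerase (-2.18 ± 0.11), Susd2 (-2.17 ± 0.28), Fam180a (-2.13 ± 0.34) and the small proteoglycan gene Fmod (-2.09 ± 0.16) completed them. Adjusted p-values of these 16 genes and of the 4 above ran from 0.0013 for Adamtsl1 to 0.0465 for Fam180a (limma).

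**Figure D2:**
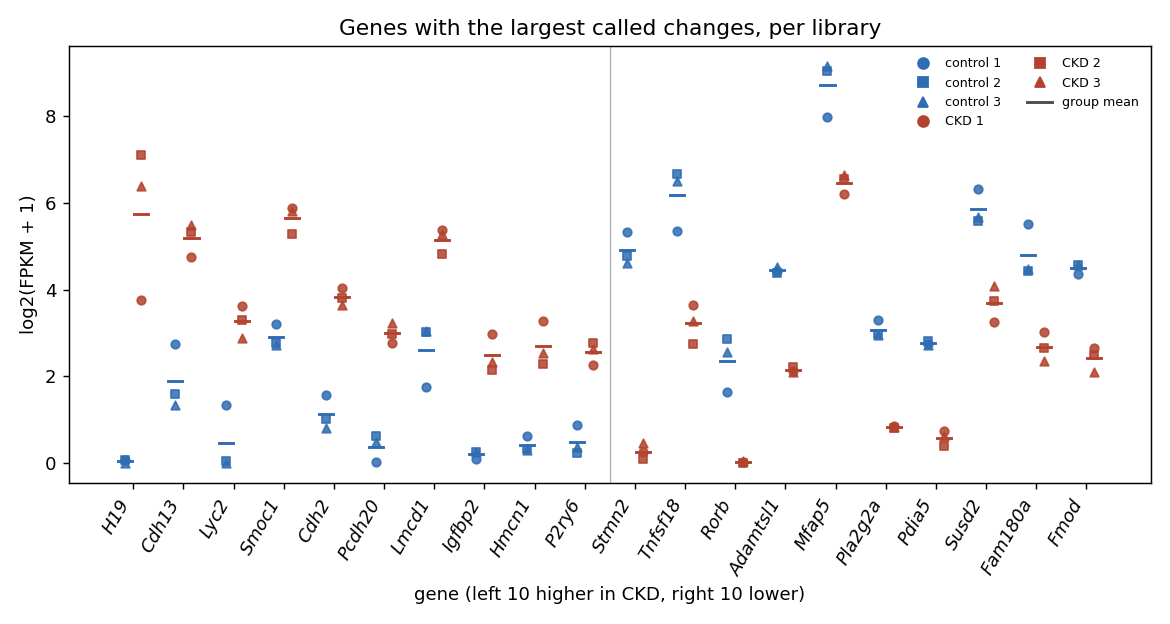
Expression of the 20 genes with the largest called changes, as log2(FPKM + 1) on the y axis with the genes along the x axis. Points are single libraries, horizontal lines are group means of 3 libraries, and in each gene the 3 CKD libraries lie on one side of the 3 control libraries.

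All 220 called genes had groups that did not overlap. Among all tested genes this held for 27.8%, where chance gives 10%. Of the called genes, 219 also had a q-value under 0.05 and the same direction in the authors' deposited table, which held 1121 higher and 768 lower genes at that level. With the absolute log2 fold change required to be at least 1, 62 higher and 31 lower genes remained. The number of calls rested on which libraries entered the fit. It fell to 3 higher and 6 lower genes without CKD replicate 2, 1 and 7 without CKD replicate 3, 1 and 6 without control replicate 2, and 1 and 5 without control replicate 3. It rose to 1139 and 463 without CKD replicate 1, to 733 and 546 without control replicate 1, and to 237 and 61 without both libraries whose disease model tag goes against their other labels. Grouped by that tag, no gene was called by limma, and 641 had an unadjusted p under 0.05. Of the 35 called genes that are named here, Stmn2, Adamtsl1, Pla2g2a and Pdia5 were called without each library in turn. The number called was 5 without CKD replicate 2, 5 without CKD replicate 3, 4 without control replicate 2 and 4 without control replicate 3, and 35 without CKD replicate 1 or control replicate 1, while in all 6 of these fits the log2 fold changes stayed between 0.834 and 1.19 times their values. Of the 35, 20 were called without a filter on low values, 28 with a pseudocount of 0.1 and 19 without both libraries with conflicting tags. The number was 17 with the replicate number as a block, 22 in limma-voom on recovered counts and 7 with the haematopoietic list mean as a covariate. With groups by the disease model tag, their log2 fold changes fell to between 0.0864 and 0.618 times their values.

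Of the 31 lists fixed in advance, 25 had enough tested genes and 5 passed the list test (camera), while 0 passed with an estimated correlation and 0 in fry's test for a shared direction. Fry's mixed test, added after seeing the data, asks whether genes change in either direction and does not compare a list with other genes, and 12 lists passed it. Genes of the cell cycle gave the clearest group. All 25 tested proliferation genes had a positive log2 fold change, with a median of 1.26 (camera adjusted p = 7.04e-16), and 9 were called over all genes and 24 when adjusted over the list alone. The list call was lost with an estimated correlation (p = 0.107, adjusted p = 0.970) and with fry (adjusted p = 0.0603). Plk1, a mitotic kinase, averaged 7.64 ± 0.878 FPKM in CKD and 2.04 ± 0.626 in control (log2 fold change 1.52 ± 0.18 SE, limma adjusted p = 0.0297), and the mitotic kinase gene Aurka averaged 3.48 ± 0.618 against 1.03 ± 0.167. The replication helicase genes Mcm3 (log2 fold change 1.35 ± 0.18) and Mcm2 (0.62 ± 0.08) rose as well. The 25 genes were all higher in CKD replicate 1 than in control replicate 1, where markers of haematopoietic cells were not higher. No single gene of the list was called when CKD replicate 2, CKD replicate 3, control replicate 2 or control replicate 3 was left out, although all 25 log2 fold changes stayed positive in each of those fits. The list median was 0.82 with groups by the disease model tag (camera adjusted p = 3.51e-06) and 1.05 with the haematopoietic list mean as a covariate (camera adjusted p = 2.26e-14).

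Genes of cholesterol and sterol synthesis were lower in CKD as a list. Of 17 tested, 16 had a negative log2 fold change, with a median of -0.33 (camera adjusted p = 1.08e-08). With an estimated correlation the list had p = 0.0353 and an adjusted p of 0.882, and fry gave an adjusted p of 0.0603. The median shrank to -0.21 with the haematopoietic list mean as a covariate (camera adjusted p = 8.07e-05) and to -0.16 with groups by the disease model tag (camera adjusted p = 0.00242). None was called over all genes by limma, 13 had an unadjusted p under 0.05 in the lower direction, and 7 were lower when adjusted over the list alone. Limma-voom on recovered counts called none either, while limma-voom with sample quality weights called 15 lower and 1 higher. Over all 10638 tested genes, the weighted fit called 2685 higher and 2911 lower. None of the 17 genes was higher in CKD replicate 1 than in control replicate 1.

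Markers of haematopoietic cells and macrophages were high in part of the CKD libraries. All 15 tested genes of that list had a positive log2 fold change, with a median of 3.16 (camera adjusted p = 0.000413). The list call was lost with an estimated correlation (adjusted p = 0.970) and with fry (adjusted p = 0.289), and limma called none of the genes, with 9 at an unadjusted p under 0.05. Limma-voom on recovered counts called 0 and limma-voom with sample quality weights 15, in a fit that called 2685 higher and 2911 lower genes over all. The median over these genes was 70.8 and 59.1 FPKM in CKD replicates 2 and 3, 3.92 in CKD replicate 1, 12.1 in control replicate 1, and 0.290 and 0.152 in control replicates 2 and 3. Ptprc, which encodes CD45, stood at 15.5 and 11.4 FPKM in CKD replicates 2 and 3, 0.783 in CKD replicate 1, 1.33 in control replicate 1 and 0.0140 and 0.0204 in the other controls (limma adjusted p = 0.201). None of the 15 was higher in CKD replicate 1 than in control replicate 1. The cultures had been described as negative for CD45 and CD34 and positive for CD29 and CD90 by flow cytometry. Cd34 did not reach the filter, with at most 1.20 FPKM in any library. Itgb1 (CD29) averaged 969 ± 125 FPKM in CKD and 1114 ± 115 in control, and Thy1 (CD90) 540 ± 33.8 and 728 ± 119. Neither passed the threshold (limma adjusted p = 0.435 and 0.183). Their q-values in the authors' deposited table were 0.373 for Itgb1 and 0.0417 for Thy1, which was lower in CKD there.

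Genes of hypoxia and glycolysis followed the same libraries. Of 19 tested, 17 had a positive log2 fold change, with a median of 0.59 (camera adjusted p = 0.0174; adjusted p = 0.970 with an estimated correlation and 0.420 with fry). Limma called none, with 6 at an unadjusted p under 0.05 in the higher direction, and limma-voom called 0 without and 15 with sample quality weights. The weighted fit called 2685 higher and 2911 lower genes over all. All 19 were higher in CKD replicates 2 and 3 than in control replicates 2 and 3 on average, and 7 were higher in CKD replicate 1 than in control replicate 1. The list lost its call without CKD replicate 2 (median 0.41, adjusted p = 0.107), CKD replicate 3 (median 0.44, adjusted p = 0.0808) or control replicate 1 (median 0.62, adjusted p = 0.0664), and without CKD replicate 1 its median was 1.03 (adjusted p = 1.93e-08). With the mean of the haematopoietic list as a covariate, a fit added after seeing the data, its median was 0.024 (adjusted p = 0.851). With groups by the disease model tag it was 0.78 (camera adjusted p = 9.23e-06), larger than the 0.59 between CKD and control.

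The immediate early genes passed as a list in the lower direction. Of 17 tested, 13 had a negative log2 fold change, with a median of -0.14 (camera adjusted p = 0.0398; adjusted p = 0.970 with an estimated correlation and 0.495 with fry). Nr4a1, an orphan nuclear receptor, was the 1 called member, at 51.7 ± 3.84 FPKM in CKD and 86.8 ± 6.75 in control (log2 fold change -0.74 ± 0.10 SE, limma adjusted p = 0.0396). The list lost its call without control replicate 1 (median -0.041, adjusted p = 0.877), CKD replicate 2 (median -0.14, adjusted p = 0.147) or CKD replicate 3 (median -0.20, adjusted p = 0.0808). Its median was larger in size without CKD replicate 1 (-0.28, adjusted p = 0.0197), control replicate 2 (-0.36, adjusted p = 0.00348) or control replicate 3 (-0.35, adjusted p = 0.00301), without both libraries with conflicting tags (-0.48, adjusted p = 0.00351) and with the haematopoietic list mean as a covariate (-0.48, adjusted p = 0.00806). With groups by the disease model tag it was larger in size too, at -0.35 (camera adjusted p = 0.000294). The call was also lost with libraries scaled by size factors (0.212, median -0.22) or upper quartile (0.178, median -0.20), and in limma-voom without (0.243) and with sample quality weights (0.505). Without both first replicates its median was -0.022 (adjusted p = 0.456). The call of Nr4a1 was lost without both libraries with conflicting tags (limma adjusted p = 0.0768), with libraries that share a name start summed (0.0537) and with the covariate (0.180).

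**Figure D3:**
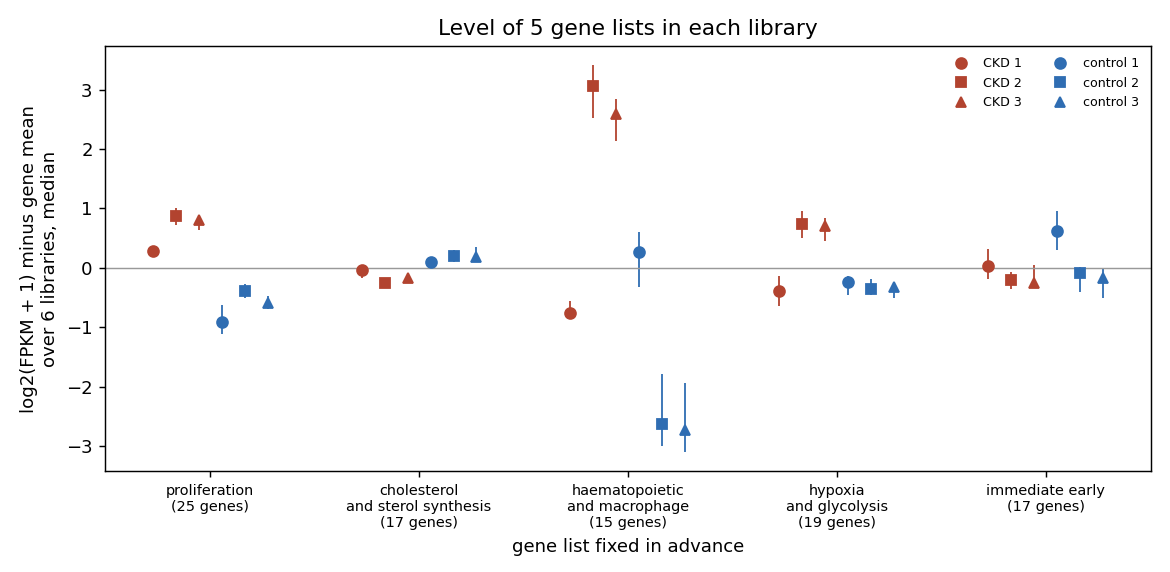
Level of the 5 lists that passed the list test, with the lists on the x axis and, on the y axis, the median over a list's genes of log2(FPKM + 1) minus the gene's mean over 6 libraries. Each point is a library and bars span the quartiles over genes. Haematopoietic and macrophage genes reach 3.06 and 2.59 in CKD 2 and CKD 3 and -0.76 in CKD 1.

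Calcification is the process the series is about, and neither list tied to it, of bone formation or of calcification inhibitors, passed the list test. In fry's mixed test both passed (adjusted p = 0.0445 and 0.00251). Among 10 tested genes of osteoblasts and mineralization, Omd, a small proteoglycan of bone, was the 1 called member, and it was lower in CKD (log2 fold change -1.21 ± 0.20 SE, limma adjusted p = 0.0471; camera adjusted p of the list 0.651). Runx2, the master transcription factor of osteoblasts, had a log2 fold change of 0.076 ± 0.32, Alpl, a phosphatase of mineralization, 0.99 ± 0.84 and Spp1, which encodes osteopontin, 0.92 ± 0.55, and none of these passed (limma adjusted p = 0.914, 0.524 and 0.374). Sp7 and Bglap did not reach the filter. Of 13 tested genes of calcification inhibitors and phosphate handling, 2 were higher in CKD (camera adjusted p = 0.817). They were Tnfrsf11b, which encodes the decoy receptor osteoprotegerin (67.1 ± 4.01 against 27.4 ± 7.15 FPKM, limma adjusted p = 0.0429), and the parathyroid hormone receptor gene Pth1r (1.23 ± 0.286 against 0.301 ± 0.0638 FPKM, limma adjusted p = 0.0452). These 3 calls lay close to the threshold. Omd, Tnfrsf11b and Pth1r all lost theirs without a filter on low values (limma adjusted p = 0.0678, 0.0549 and 0.0507). The same held in limma-voom on recovered counts (limma-voom adjusted p = 0.0553, 0.0568 and 0.0524). It also held with the haematopoietic list mean as a covariate (limma adjusted p = 0.306, 0.254 and 0.112). Limma-voom with sample quality weights called all 3, in a fit that called 2685 higher and 2911 lower genes over all. Omd and Pth1r also lost theirs with a pseudocount of 0.1 (limma adjusted p = 0.0576 and 0.0522) and with libraries scaled by size factors (0.0501 and 0.0540) or upper quartile (0.0567 and 0.0586), Tnfrsf11b and Pth1r without both libraries with conflicting tags (0.105 and 0.0795), and Pth1r with libraries that share a name start summed (0.0706). Without CKD replicate 2, CKD replicate 3, control replicate 2 or control replicate 3 no gene of either list was called, with limma adjusted p-values of 0.202, 0.229, 0.191 and 0.210 for Omd, 0.196, 0.223, 0.153 and 0.197 for Tnfrsf11b, and 0.199, 0.229, 0.183 and 0.210 for Pth1r. The direction held in all these fits. Over those that lost a call, the log2 fold change ran from -1.66 to -0.89 for Omd and from 0.67 to 1.96 for Pth1r. For Tnfrsf11b it was 1.09 or more. With groups by the disease model tag all 3 were uncalled and smaller, at -0.69 for Omd, 0.12 for Pth1r and 0.29 for Tnfrsf11b. Mgp, which encodes an inhibitor of calcification, averaged 158 ± 51.8 FPKM in CKD and 1282 ± 821 in control. It did not pass (log2 fold change -2.74 ± 0.70 SE, limma adjusted p = 0.111). The authors' deposited values for Mgp were a log2 fold change of -3.11 and a q-value of 8.88e-06. Missing the threshold in limma thus does not show that Mgp was unchanged.

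Among the other lines of differentiation, none of the 11 tested adipocyte genes was called by limma (5 higher and 1 lower at an unadjusted p under 0.05), although 3 were higher when adjusted over the list alone (camera adjusted p = 0.586). Pparg, the main regulator of fat cell formation, averaged 2.29 ± 0.259 FPKM in CKD and 0.613 ± 0.463 in control (limma adjusted p = 0.0881). The cartilage factor Sox9 had a log2 fold change of 0.14 ± 0.55 (limma adjusted p = 0.907), and the chondrocyte list was too small to test, since 4 of its 11 genes in the table passed the filter on low values. In the list of stromal identity, Nes, which encodes the intermediate filament nestin, was higher in CKD (2.24 ± 0.823 against 0.219 ± 0.217 FPKM, limma adjusted p = 0.0471) and the other 17 genes were not called. The call of Nes was lost without a filter on low values (limma adjusted p = 0.0647), with a pseudocount of 0.1 (0.0585), without both libraries with conflicting tags (0.0682), with libraries that share a name start summed (0.0555), in limma-voom on recovered counts (0.0669) and with the haematopoietic list mean as a covariate (0.183), with log2 fold changes of 0.87 or more in these fits against 1.39. With groups by the disease model tag Nes was uncalled too, with a log2 fold change of 0.61 (limma adjusted p = 0.747). All 15 smooth muscle and myofibroblast genes were uncalled, with 0 at an unadjusted p under 0.05 (limma).

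In the list of senescence and secretory genes, 2 of 22 tested were called, both higher in CKD (camera adjusted p = 0.622). They were Igfbp2 and Lmnb1, a nuclear lamina gene whose product is lost in senescent cells (7.79 ± 1.41 against 2.75 ± 0.447 FPKM, limma adjusted p = 0.0355). The cell cycle inhibitors Cdkn1a and Cdkn2a had log2 fold changes of -0.34 ± 0.24 and -0.57 ± 0.16 and did not pass (limma adjusted p = 0.441 and 0.130). In the authors' deposited table their q-values were 0.381 and 0.00976, both in the lower direction. Of the matrix and signalling lists, 4 held a called gene each and did not pass in camera. Col8a1, a short-chain collagen, was lower (log2 fold change -0.87 ± 0.11), as were the Wnt receptor gene Fzd1 (-0.94 ± 0.10) and the BMP antagonist gene Chrd (-1.51 ± 0.25), while the protease gene Adamts12 was higher (10.3 ± 0.589 against 3.84 ± 0.388 FPKM). Their limma adjusted p-values were 0.0355, 0.0219, 0.0498 and 0.0113, and the camera adjusted p-values of their lists were 0.875 for matrix and fibrosis, 0.717 for Wnt signalling, 0.137 for BMP and TGF-beta feedback and 0.717 for matrix proteases. The calls of Col8a1 and Fzd1 were lost without both libraries with conflicting tags (limma adjusted p = 0.0709 and 0.0568), that of Col8a1 with libraries that share a name start summed (0.0532), and those of Col8a1, Fzd1 and Chrd with the haematopoietic list mean as a covariate (0.180, 0.135 and 0.290). Chrd also lost its call without a filter on low values (limma adjusted p = 0.0681), with a filter on CPM (0.0501), a pseudocount of 0.1 (0.0588), size factors (0.0508) or upper quartile scaling (0.0561) and in limma-voom (0.0553), while Adamts12 kept its call in each of these fits. Fry's mixed test gave adjusted p-values of 0.00251, 3.73e-05, 0.0675 and 1.12e-06 for these lists in the same order.

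In camera no list passed among inflammation (camera adjusted p = 0.717), type I interferon response (0.586), antigen presentation (0.511), vesicle biogenesis (0.586), oxidative stress (0.677), aryl hydrocarbon receptor targets (0.944), oxidative phosphorylation (0.586), stress response (0.944), limb and body position (0.943) or cytosolic ribosomal proteins (0.677). Of the sample checks, S100b in the Schwann cell list was lower in CKD (8.08 ± 1.70 against 16.9 ± 1.20 FPKM, limma adjusted p = 0.0462), with 2 genes of that list tested. Its call was lost without a filter on low values (limma adjusted p = 0.0647), with a pseudocount of 0.1 (0.0514), without both libraries with conflicting tags (0.0603) and with the haematopoietic list mean as a covariate (0.183), with log2 fold changes between -1.19 and -0.81 against -0.99. With groups by the disease model tag S100b was uncalled too, with a log2 fold change of -0.086 (limma adjusted p = 0.959). The endothelial list had 2 genes tested and the skeletal muscle list 3, with 0 called in either, and no mitochondrially encoded gene was in the table. Xist was at most 0.135 FPKM and the Y-linked gene Eif2s3y 40.2 FPKM or more in all 6 libraries.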

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

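Tests of the scaling, of CKD replicate 1 against control replicate 1 and of the disease model tags, and the counts of genes and lists over other splits, were chosen only after the result had been seen. Myod1, a muscle transcription factor, and 17 other genes lay outside the tested set but reached at least 1 FPKM in 2 CKD libraries while staying at or under 0.05 FPKM in all 3 controls, 18 genes in all. Signal above the controls in genes that the filter on low values had left out drew attention to them, and in each case the libraries were CKD replicates 2 and 3. Myod1 stood at 4.33 and 4.04 FPKM there and at 0.0133 in CKD replicate 1, and was listed at 0 in the controls. Genes of immune cells were among them, with the macrophage receptor gene Cd163 at 7.89 FPKM or more in both, Cd8a at 7.93 and 5.08, Fcrl2 at 4.92 and 1.74, Mmp8 at 1.80 and 1.40 and Ly49si3 at 1.19 and 1.30. Others were Scin, an actin-severing protein, at 6.71 and 10.2 FPKM, Igf2 at 4.91 and 3.51, Barx1 at 3.35 and 3.00, and the muscle cadherin gene Cdh15 at 1.66 and 1.05. The reverse rule gave 2 genes for the controls. Genes at 1 FPKM or more in all 3 CKD libraries had passed the filter, so a low value in 1 CKD library was built into the rule for the 18. Only which CKD library was low could vary.

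Haematopoietic and macrophage genes were high in CKD replicates 2 and 3. Upper quartile scaling left a median log2 difference of 5.60 between these libraries and control replicates 2 and 3, which argues against scaling as the cause. Cells of haematopoietic origin, or their RNA, in these libraries are a candidate explanation. Of 26 myeloid genes in a second list, 92.3% were higher in both libraries than in each of the other 4, with 6 of the 26 at 1 FPKM or more in control replicates 2 and 3 as well, and abundant myeloid genes stood high, with Lyz2 at 2224 and 1473 FPKM and Ctss at 233 and 155, although the cultures were described as negative for CD45 by flow cytometry. An effect of CKD on the cells also stays open, with a median log2 difference of -0.83 between CKD replicate 1 and control replicate 1, since a single pair of libraries excludes nothing.

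The disease model tags put CKD replicate 1 among the controls and control replicate 2 among the CKD libraries. Positions were taken on the 298 genes called without both, with the other controls at 0 and the other CKD libraries at 1. Control replicate 2 had a median position of 0.0403. It was nearly alike to control replicate 3 (r = 0.998), which helped to set the 0 point and the choice of genes. The position thus restates that likeness, and it argues against a swap only if control replicate 3 is itself a control. CKD replicate 1 had a median position of 0.391 (quartiles 0.0645 and 0.685). A control library under a wrong title could not be excluded for it, nor could a CKD library that differs from the other 2. No biological explanation was tested for this pattern.

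Proliferation genes were higher in CKD by a median log2 fold change of 1.26. Gene length or expression level did not account for it, since the list median lay at percentile 100 of 10000 lists matched on both, and neither did the scaling, since the lower median under 2 other scalings was 1.20. Dividing haematopoietic cells in CKD replicates 2 and 3 are argued against as the whole cause by a median of 1.05 with the haematopoietic list mean as a covariate, with all 25 genes positive. In that fit the calls went from 9 to 0 while the median standard error rose from 0.22 to 0.34. An effect of CKD, and differences in density or passage of the cultures, stay open and untested.

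The comparison of CKD with control called 220 genes, and the highest number in the other splits of the 6 libraries was 17. That other split set CKD replicate 1 and control replicates 2 and 3 against the rest. At an unadjusted p under 0.05 (limma) the contrast was smaller, with 1504 genes in that split and 2354 in the real one. As many genes were called in 1 of the 10 splits, the real one, and 10 splits are too few to give a share under 0.05. For the lists, 7 of the 10 splits took at least as many past the threshold as the real 5, and the highest other number was 16, for CKD replicate 1, control replicate 1 and control replicate 3 against the rest, which is the grouping by the disease model tag. Splits that take more lists past the threshold than the real one point to a structure of the libraries beside the groups. These splits are likewise too few for a share under 0.05.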

How the results depend on the processing

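Alternatives named here as added were chosen after seeing the data. In the order higher, lower, the 142 and 78 called genes became 62 and 31 with an absolute log2 fold change of at least 1, 0 and 0 with groups by the disease model tag, and 2685 and 2911 in limma-voom with sample quality weights. Without a filter 81 were higher, and without both libraries with conflicting tags 237 were. Among added alternatives, limma-voom without weights gave 61 higher, a term for the first replicates 661 and 424, leaving out both first replicates 3689 and 2162, and the haematopoietic covariate 6 and 11. The fit without both first replicates rests on the 2 alike pairs alone. Whether their members are independent is open, so its p-values may measure technical spread. Which libraries the sample quality weights favoured is not given here, so the 2685 and 2911 calls are not firmer than the main ones. Leaving out CKD replicates 2 and 3, also added, gave 0 and 0 with 1167 genes at an unadjusted p under 0.05, but it leaves a single CKD library, assumed to vary like the controls, and so decides nothing about dependence. Without 1 library in turn, the counts ran from 1 to 1139 higher and from 5 to 546 lower. Counts stayed within 1.5 times under the other alternatives except the replicate block, given below, with 126 and 104 under size factors, 136 and 87 under upper quartile scaling, both added, and 180 and 82 with libraries that share a name start summed. The 5 lists became 16 with groups by the tag, 8 without the libraries with conflicting tags, 8 without both first replicates, and 0 with an estimated correlation or fry's test for a shared direction and 12 in fry's mixed test, added, and ran from 3 to 8 without 1 library. Fits without libraries rest on fewer samples and on another spread within groups, and beyond that the cause was not tested.

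Deviations from the group mean of same-numbered libraries correlated at 0.036, -0.031 and 0.109, so they showed no pairing by replicate number. Such correlations do not exclude a shift shared by the first replicates. On the second principal component CKD replicate 1 and control replicate 1 lay at -28.8 and -30.6, against 10.6 or more in the other libraries. With the replicate block, 60 genes were higher and 28 lower, and 5 lists passed. Of the 35 called genes that are named, 17 kept their call in that fit. Omd, Tnfrsf11b and Pth1r were not called in it (limma adjusted p = 0.0720, 0.0616 and 0.102). Nor were Nes, S100b, Col8a1, Chrd and Nr4a1 (limma adjusted p = 0.115, 0.0581, 0.0600, 0.0874 and 0.0776). Fzd1 and Adamts12 were called in it (limma adjusted p = 0.0485 and 0.0495). Replicate numbers follow the column codes, and by its title, which carries a 4, CKD replicate 3 has no partner. Not every library correlated best with its own number.

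Among named genes and the medians of the 5 lists that passed, 706 values kept direction and side of the threshold and 326 kept direction and lost the threshold. Another 31 gained it and 17 changed sign, the last each uncalled in that setting. Medians of the other lists were not counted. That of the osteoblast list, for example, went from -0.032 to 0.22 without control replicate 1. Runx2 ran from -0.15 to 0.45 without 1 library, with -0.070 and -0.15 without control replicate 2 or 3, and went to -0.21 by the tag, -0.10 without conflicting tags and -0.39 with the haematopoietic covariate. Sox9 ran from -0.35 without CKD replicate 1 to 0.58, with -0.11 and -0.045 without control replicate 2 or 3, and went to -0.95 by the tag and -0.61 without conflicting tags. Alpl went to -1.05 by the tag and -0.048 without conflicting tags, Mgp to 0.042 by the tag, Itgb1 to 0.086 and Spp1 to -0.16 with the covariate, and, with the single CKD library, Spp1 to -0.38 and the hypoxia list median to -0.071. Planned fits of edgeR and DESeq2, with their scalings, were not run, and the recovered counts entered limma-voom alone. Depth limits values near 0.02 FPKM. With 3 libraries per group, the number of calls varied with which libraries entered the fit. Without 1 library, the 35 named called genes kept between 0.834 and 1.19 times their log2 fold changes. Their calls thus changed with the estimated spread and the number of libraries more than with the size of the change. Replicates 2 and 3 of each group were an alike pair. A fit without a first replicate took that group's spread from such a pair, and a fit without replicate 2 or 3 took it from 2 unlike libraries.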

Other observations

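Both first replicates shared a profile that the comparison of groups does not describe. Alpl stood at 40.7 and 19.4 FPKM in CKD replicate 1 and control replicate 1, and between 3.56 and 9.22 FPKM in the other 4 libraries. Ibsp, which encodes bone sialoprotein, stood at 4.17 and 6.72 FPKM against at most 0.869, the bone transcription factor gene Dlx5 at 3.96 and 3.20 against at most 0.704, and Sox9 at 8.44 and 6.96 against at most 2.46. Col1a1, the main collagen of bone, stood at 5299 and 5881 FPKM against at most 3000 in the others. In the unfolded protein and integrated stress response list, 10 of 18 tested genes were higher in both first replicates than in each other library, as were 8 of 17 in the immediate early list, which passed as lower in CKD, 5 of 10 in the osteoblast list and 8 of 27 in the matrix and fibrosis list. These genes were chosen after their values were seen, and no test was made between libraries grouped in this way.

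CKD replicates 2 and 3 held some transcripts at far higher levels than the remaining CKD library. Stc1, a hormone of calcium and phosphate balance, stood at 80.9 and 89.4 FPKM in them and at 0.865 in CKD replicate 1, with at most 3.58 in the controls. The chemokine gene Cxcl6 stood at 192 and 171 FPKM and at 0.0277 in CKD replicate 1, the intermediate filament gene Des at 33.7 and 36.2 and at 0.729, and the fatty acid binding protein gene Fabp4 at 95.1 and 93.0 and at 4.18. Loxl2, an enzyme of collagen crosslinking, was highest in CKD replicate 1, at 233 FPKM, with 79.2 and 89.4 in CKD replicates 2 and 3 and at most 91.3 in the controls.

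A hypothesis that imprinted genes as a group were higher in CKD, raised by H19, was tested on a list of 22 imprinted genes written before its result was seen. Of 11 tested, 63.6% had a positive log2 fold change, the median was 0.13, none was called by limma, and camera (limma) gave an adjusted p of 0.991 over this 1 list. That share lies between the bounds set beforehand for a rise and for none. A camera p that misses the threshold had also been set beforehand as a result against a rise. By that bound, with 0.991, the hypothesis failed. The bound on p is set aside here, since such a p, with members going both ways, excludes nothing and was the wrong bound to set. By the share alone the question stays open. The 11 were those of 20 in the table that passed the filter on low values, which left out Igf2, at 4.91 and 3.51 FPKM in CKD replicates 2 and 3 and at most 0.0404 in the controls.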
